A study of Homo sapiens with 16 samples.

How the data were processed

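POP-seq and its UV-crosslinked form were applied to cultured cells of 6 lines, per the labels' protocols. Cells were lysed in trizol, the interphase was digested with RNases A and T1, and the RNA released from protein was depleted of ribosomal RNA before library preparation. The 16 samples form 8 groups of 2 replicates: 6 lines without crosslinking, and HepG2 and K562 also with UV. Groups were taken from the sample titles and source names. The labels do not say whether replicates came from separate cultures.

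The data are 8 peak lists, 1 per group, taken as pooled over the replicates. Each peak has a chromosome, start, end, name, strand, score and p-value. HISAT2, SAMtools 1.9, bedtools 2.18.1 and the build hg38/GRCh38 are named in the submitters' processing notes without their roles. The peak caller, its threshold and how replicates were joined are not given in the sources used here. The deposited score is a number per peak whose origin is not stated: its top value is 60 in the non-crosslinked lists and 255 in the UV lists, and 96.8% to 99.6% of peaks hold it. The mapping quality that HISAT2 writes ends at 60; whether the score is one, and whether the UV lists came from the same aligner and reference sequences as the others, is not given in the sources used here. The deposited p-value is the same for over 96% of peaks in each of 7 lists. In the HepG2 non-crosslinked list the values differ and 99.2% of the p-value column is below 0, so the authors' column was not read as a p-value there. Score and p-value were used only to filter peaks within a list. Between 47.6% and 57.7% of peaks are named X and the rest carry a read identifier; from these identifiers only the number of flow cells (2) and which lists share one were taken.

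Peaks were placed by their midpoint in gene spans of the RefSeq table for GRCh38.p14 (59701 genes on chromosomes 1 to 22, X, Y and M). Small and structured RNAs came first, then protein-coding genes, then other genes, and the shorter gene among equals; the plan had put protein-coding genes first. TALAM1, which spans MALAT1, was dropped. The table holds no strand, exons or sequence. Exon, intron and UTR classes, the planned exonic share, exon-only counts, base composition and motifs were therefore not analysed here, and class shares are given by gene type in place of the planned classes. Levels of Y-linked genes, XIST and TSIX are not reported.

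Overlap needed 1 base on the same strand. Each genic peak of the smaller list was moved at random within its gene 200 times, and a two-sided p was taken from the shuffles. Sites common to lines are merged peaks of the 6 non-crosslinked lists. Densities are peaks per 10000 peaks of the list. Shares have 95% Wilson intervals, differences Newcombe intervals and ratios exact conditional intervals, all for counting error only; a count of 0 was taken as 3 in ratios. The strand of a gene was inferred where the other 7 lists held 10 or more peaks, at least 90% on the same strand.

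The 26 gene lists, the marker lists among them, the tests of overlap, the ranking of gene lists and the rule for named genes were fixed before the data were examined. Strand and gene ends, flow cells, overlaps of UV lists with other lines, UV ratios of gene lists, RNA classes with UV, tRNA genes and regions without UV peaks were analysed after the data had been seen. The lists cover housekeeping groups, RNA-binding proteins, structured RNAs, lncRNAs, markers of the 6 lines and genes of other tissues. For 22 of them, the share of genes with a peak was ranked among 10000 random lists drawn from the 100 genes of the same class nearest in length. Named genes were the 10 with the highest minimum density over the non-crosslinked lists, the 4 per line with the most peaks and none in the other 5 lines, the 8 highest and 8 lowest UV ratios per line among genes with 10 or more peaks, and the 3 members per list with the most peaks. Other genes named were chosen after their values were seen: those with most sites in all lines, those in regions without UV peaks, and those in the further observations.

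Tested on simulated data from the HepG2 non-crosslinked list (26632 genic peaks, 10 runs each), the overlap test recovered 29.8% to 30.3% of peaks where 30% were planted. With none planted it recovered -0.176% to 0.213%, and 1 of 10 runs gave p under 0.05. With none planted but the peaks kept at their deposited, clustered positions, it recovered -0.375% to 0.117% and 6 of 10 runs gave p under 0.05, so p is too small for differences of that size. Of 200 random lists of 50 genes, 3.5% fell outside the central 95% range, and 200 of 200 lists with peaks in 80% of genes lay above it.

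The alternatives were merged peaks, bases in place of midpoints, an overlap of 50% of both peaks, strand ignored, each line left out and lists thinned to the smallest. Added after seeing the data were peaks named X alone, shifts of 200 to 1000 bases, leaving out peaks of p above 0.05 or stretches without UV peaks, and top scores alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.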

Results

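Protein-occupied RNA fragments were profiled across 6 human cell lines with POP-seq. In this assay, RNA that stays with protein at the trizol interphase is trimmed with RNases A and T1, freed from the protein and sequenced. The lines were A549 (lung carcinoma), HEK293 (embryonic kidney), HepG2 (liver carcinoma), Jurkat (T cell leukaemia), K562 (chronic myeloid leukaemia with erythroid features) and MCF7 (luminal breast carcinoma). All 6 were profiled without crosslinking, and HepG2 and K562 also after UV irradiation at 254 nm with 400 mJ per square cm. Each of the 8 groups had 2 replicates, 16 samples in all, and 1 deposited peak list per group. No value was therefore held per replicate, no difference between groups was tested against replicate spread, and all intervals below cover counting error only.

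The non-crosslinked lists held 54143 peaks in A549, 81889 in HEK293, 29908 in HepG2, 83831 in Jurkat, 24115 in K562 and 84146 in MCF7. The UV-crosslinked lists held 37462 peaks in HepG2 and 60096 in K562. Peaks were short, with median widths from 42 to 50 bases and a full range from 5 to 250 bases. Between 9148 genes (K562) and 15187 genes (HEK293) carried at least 1 peak in a non-crosslinked list, against 12399 in the HepG2 and 13510 in the K562 UV list. Read depth was not analysed here, and whether the number of peaks follows it is not known.

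Protein-coding genes held most of the peaks. They took from 77.7% (95% Wilson interval 77.2–78.2) of peaks in K562 to 87.2% (86.9–87.4) in MCF7 among the non-crosslinked lists. Small and structured RNAs, a class that joins snoRNAs, snRNAs, tRNAs and microRNA precursors, held from 1.40% in Jurkat to 4.39% in K562. Per Mb of gene span they held the most peaks, 1086 to 1679 over the 8 lists, against 14.8 to 58.1 in protein-coding genes. The spans are unlike, and no like-for-like density was taken. The 1263 Mb of protein-coding genes include introns, and the 0.892 Mb of small RNAs took every peak where both overlap. Long non-coding RNA genes held 3.12% to 5.32% of peaks, and 7.24% to 11.8% of peaks lay outside annotated gene spans.

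Peaks lay mostly on the strand inferred from the other lists and gathered at gene ends. Annotated strands were not available, so the strand of a gene was inferred from the other 7 lists. Genes with few peaks or mixed strands there were left out. In the protein-coding genes kept, 95.3% (Jurkat) to 97.4% (MCF7) of peaks lay on the inferred strand. These shares measure agreement between lists in genes chosen for such agreement. The transcribed strand itself was not compared. In genes of 20 kb or more, the first 1 kb held 5.52% (MCF7) to 9.05% (K562 UV) of peaks, where 1.76% to 1.94% would fall by length alone. The final 2 kb by the inferred strand held 10.4% (10.1–10.7) of peaks in Jurkat and 16.7% (16.3–17.1) in MCF7. HepG2 without crosslinking stood above all other lists there with 21.8% (21.0–22.5), and the HepG2 UV list had 12.3% (11.8–12.8).

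The first comparison asked how far occupied sites were shared between cell lines. Sites held by all 6 non-crosslinked lines numbered 1746 of 237001 merged sites, and 175965 sites (74.2%) occurred in a single line. These counts depend on the size of the lists: 21 sites were common to all lines with the lists thinned to the smallest, and 3158 with HepG2 left out. FLNA, which encodes an actin-crosslinking protein, carried the most sites common to all lines, with 9. IRF2BP2, a transcriptional corepressor gene, the spliceosome core gene PRPF8, the amino acid transporter subunit gene SLC3A2, the splicing factor gene SRSF1 and the 14-3-3 gene YWHAG carried 4 each. Small and structured RNAs made up 15.4% of the sites common to all lines, and protein-coding genes 72.5%. Within genes, 1608 such sites were seen where shuffling every list within its genes gave a mean of 279 and a range from 260 to 296. The shuffles spread peaks over whole gene spans, introns included. Lists that only share exons or gene ends would exceed them as well.

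Every pair of lines shared more positions than the same peaks shuffled within their genes. Without exon positions these shuffles put peaks in introns too, so peaks gathered in the same exons or gene ends raise the fold. The test cannot separate this from shared positions within exons. Of the 15 pairs, 15 passed with an adjusted p of 0.00995 (Benjamini-Hochberg over the 15 positional permutation tests, two-sided), the smallest value that 200 shuffles can give. Between 22.4% and 41.8% of the peaks of the smaller list overlapped a peak of the other, from 4.81-fold to 6.81-fold above shuffled peaks, with a median of 5.51-fold. The percentages depend on list size: with all lists thinned to the smallest, 6.31% of Jurkat peaks overlapped MCF7 and 20.3% of K562 peaks overlapped HepG2. Thinning takes most from the largest lists, so the thinned percentages do not rank the pairs free of list size. A549 and Jurkat lay at 6.81-fold, K562 and HepG2 at 5.83-fold, Jurkat and MCF7 at 5.51-fold, and K562 and MCF7 at 4.81-fold. HepG2 and K562, in both treatments, had been sequenced on 1 flow cell and the other 4 lines on another. Pairs of lines within a flow cell lay at 5.45-fold to 6.81-fold and pairs across flow cells at 4.81-fold to 5.69-fold. Against peaks shifted by 200 to 1000 bases the ranges lay within each other, at 4.58-fold to 9.30-fold and 4.74-fold to 7.73-fold.

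**Figure D1:**
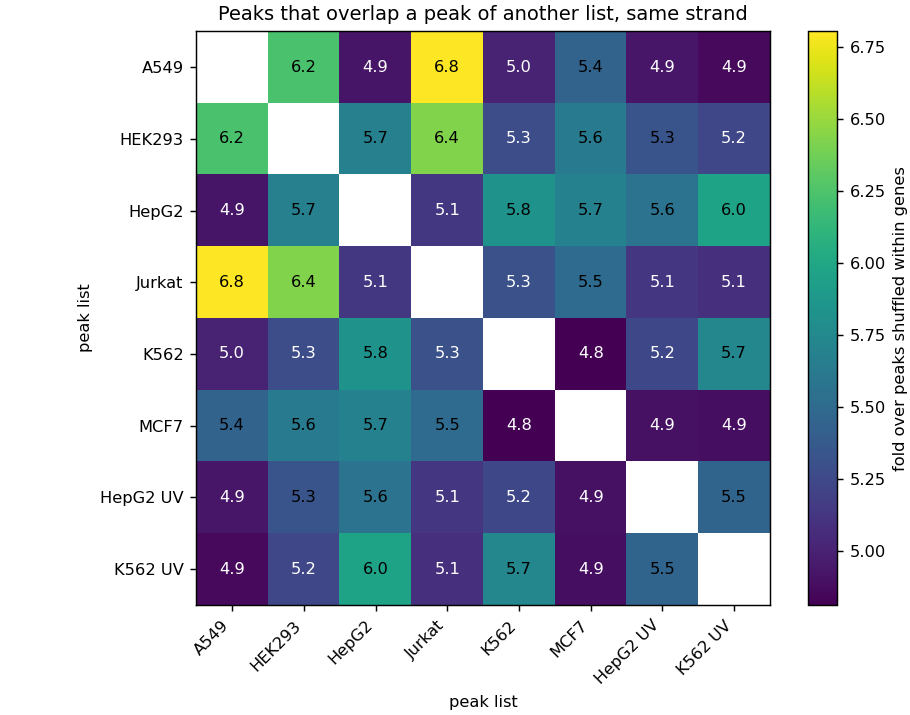
Overlap of each pair of the 8 peak lists (both axes) on the same strand, as fold over the mean of 200 shuffles of the smaller list within its genes. Among pairs of lines without crosslinking the fold runs from 4.81 (K562 and MCF7) to 6.81 (A549 and Jurkat).

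Some genes carried many peaks in all 6 lines. DYNC1H1, the dynein motor heavy chain gene (chromosome 14, 101964573–102056443), held 32 to 72 peaks per non-crosslinked list. HUWE1, a ubiquitin ligase gene, held 21 to 75, and FLNA 27 to 80. The other members of the 10 genes chosen for the highest minimum density were SON, a splicing cofactor gene, the ubiquitin ligase gene UBR4, the heterochromatin protein gene CBX5, the fatty acid synthase gene FASN, the spectrin gene SPTBN1, the clathrin heavy chain gene CLTC and the histone methyltransferase gene KMT2D. FASN ranged from 13 peaks in HepG2 to 50 in HEK293, and KMT2D from 10 in HepG2 to 70 in HEK293.

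The second comparison asked whether the lists carried the identity of each line. All 6 marker lists, fixed before the data were examined, had their highest density of peaks in their own non-crosslinked line. The MCF7 list of luminal breast genes reached 136 peaks per 10000 peaks, 7.28-fold (5.93–9.01) above the next line, with 227 peaks in the oestrogen receptor gene ESR1, 152 in its target GREB1 and 260 in BCAS3, a gene amplified in breast cancer. Jurkat's T cell genes lay 8.12-fold (5.61–12.1) above the next line, with 44 peaks in BCL11B and 36 in TCF7, both T cell transcription factor genes, and 39 in PTPRC, which encodes CD45. A549's lung and oxidative-stress genes lay 7.69-fold (5.18–11.9) above the next line, led by CYP24A1, a vitamin D hydroxylase gene, with 82 peaks, TXNRD1 with 74 and the cystine transporter gene SLC7A11 with 46. Liver genes in HepG2 lay 4.78-fold (2.63–9.37) above the next line, with 27 peaks in the apolipoprotein gene APOB and 8 in the fetuin gene AHSG. K562's erythroid and leukaemia genes lay 3.51-fold (2.69–4.57) above the next line, with 25 peaks in the transferrin receptor gene TFRC, 22 in ABL1 and 16 in BCR, the partners of this line's fusion gene. HEK293 was the exception in size: its embryonic kidney list had 13.8 peaks per 10000, against 13.0 in HepG2, a ratio of 1.06 (0.729–1.56). By the share of genes with a peak, the HEK293 list lay within the range of random lists in HEK293, and the K562 list lay above it in HepG2 (58.3%) as well as in K562 (66.7%). DACH1, a developmental transcription factor gene of the HEK293 list, had 26 peaks in HEK293, 7 in HepG2 and 0 to 2 in the other 4 lines.

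**Figure D2:**
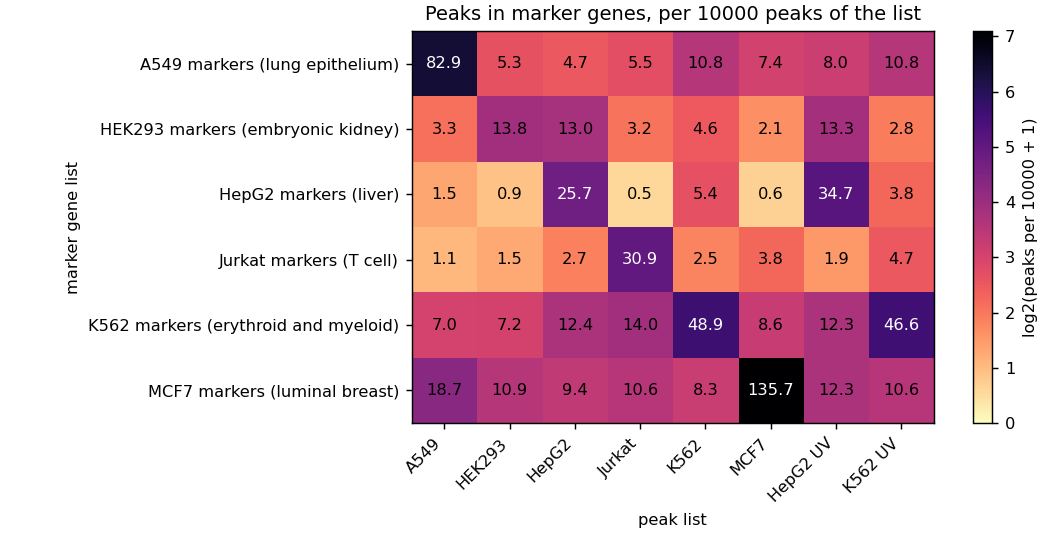
Peaks in the genes of 6 marker lists (vertical axis), per 10000 peaks of each of the 8 peak lists (horizontal axis), with the colour on a log2 scale. Each list is densest in its own line among the non-crosslinked lists, and the embryonic kidney list has 13.8 in HEK293, 13.0 in HepG2 and 13.3 in HepG2 with UV.

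Some genes had peaks in a single non-crosslinked line. Those below were chosen by their number of peaks alone, and a match with the line's lineage was not tested. In Jurkat these were led by MYO7B with 47 peaks, the haematopoietic guanine exchange factor gene DOCK2 with 32, LCP2, which encodes a T cell receptor adaptor, with 28, and RFX8 with 27. In MCF7 they were SPTSSB with 60 peaks, IQANK1 with 37, CCDC170, a neighbour of ESR1, with 29, and the prolactin receptor gene PRLR with 28. A549 had ALDH3A1, an aldehyde dehydrogenase gene, with 23 peaks, LINC02866 with 21, TGFBI with 18 and TM4SF1 with 14. HEK293 had the homeobox genes HOXD11 with 16, ZFHX4 with 12 and HOXD10 with 9, and HS3ST3A1 with 9. HepG2 had APOB with 27, AHSG with 8, and ERICH3 and ITIH2 with 5 each. K562 had OR51B5, an olfactory receptor gene beside the beta-globin cluster, with 10 peaks, ADAMTS14 and LINC01029 with 7 each, and the erythroid spectrin gene SPTA1 with 5.

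Housekeeping gene groups other than the ribosomal proteins had peaks in most of their genes. Of 176 combinations of a gene list and a peak list that could be ranked against 10000 length-matched random lists, 95 lay above and 47 below the central 95% of random lists. Translation factors had peaks in 65.7% (HepG2) to 92.5% (HEK293, Jurkat) of 67 genes over the non-crosslinked lists, with EIF4G1 and EIF3A leading. Proteasome subunits had peaks in 76.9% to 94.9% of 39 genes, the nuclear-encoded respiratory chain in 64.2% to 86.4% of 81 genes, glycolysis in 85.7% to 100% of 14 genes and the cell cycle list in 96.3% to 100% of 27 genes. Replication-dependent histone genes had peaks in 55.9% (HepG2) to 82.4% (A549) of 68 genes. The hnRNP genes had peaks in 76.7% to 86.7% of 30 genes, with 8 to 39 peaks in HNRNPH1, and the SR and SR-like splicing factors in 88.2% to 94.1% of 17 genes, with 21 to 58 peaks in SRRM2. Heat shock and chaperone genes had peaks in 73.3% (HepG2) to 100% of 15 genes. Abundant lncRNAs had peaks in 36.4% (HepG2) to 86.4% (Jurkat) of 22 genes. NEAT1, the scaffold of paraspeckles, held 106 peaks in HEK293 and 12 in Jurkat, and MALAT1, a nuclear speckle lncRNA, held 47 in K562 and 6 in MCF7. PVT1, the lncRNA beside MYC, held 171 peaks in MCF7 and 4 to 37 in the other 5 lines.

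Lists of genes from tissues not represented by the lines differed among themselves. Olfactory receptor genes had peaks in 0.513% to 1.28% of 390 genes without crosslinking, and 94 keratin-associated protein genes had none in any of the 8 lists, which allows up to 3 peaks per list. Heart and muscle genes had peaks in 2 to 5 of 20 genes, and fibroblast and endothelial genes in 5.56% to 38.9% of 18 genes. The neuron list had peaks in 2 (K562) to 12 of its 20 genes (HEK293, HepG2) and lay within the range of random lists in A549, HEK293 and HepG2. RBFOX3, a neuronal splicing factor gene, had 28 peaks in A549. In K562, 10 of the 15 olfactory receptor peaks lay in OR51B5.

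By the share of genes with a peak, the cytosolic ribosomal protein genes set the HepG2 non-crosslinked list apart. Peaks were present in 21 of these 84 genes there (95% interval 17.0–35.2%), against 78.6% (68.7–86.0) in K562 and 86.9% to 96.4% in the other 4 non-crosslinked lines. The HepG2 UV list had peaks in 86.9% (78.1–92.5) of them. By density MCF7 was low as well. Its ratio to the other lists, HepG2 without crosslinking left out, was 0.495 (0.433–0.565). That of HepG2 without crosslinking was 0.286 (0.209–0.383). RACK1, a scaffold protein gene of the small subunit, had 0 peaks in HepG2 without crosslinking and 8 with UV. The HepG2 list also held the lowest shares of snoRNA and scaRNA genes, 25.9% of 568 genes against 48.6% to 57.0% in the other 5 lines. It had 0 peaks in the 37 mitochondrially encoded genes, of which 16.2% (A549, HEK293) to 54.1% (K562) had peaks in the other non-crosslinked lists.

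**Figure D3:**
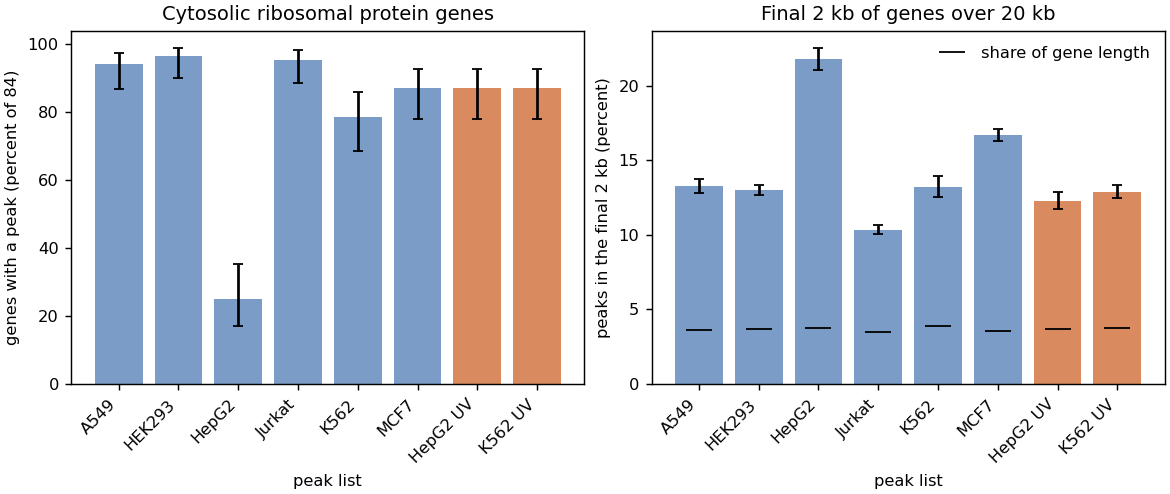
Left, percent of the 84 cytosolic ribosomal protein genes with a peak in each list. Right, percent of peaks in the final 2 kb, by the inferred strand, of genes of 20 kb or more, with dashes for the share of gene length. Bars are shares with 95% Wilson intervals, blue without crosslinking and orange with UV. HepG2 without crosslinking is lowest on the left (21 of 84 genes) and highest on the right (21.8%).

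Structured non-coding RNAs were occupied in every line. The telomerase RNA gene TERC carried 2 to 4 peaks in each list and the vault RNA gene VTRNA1-1 1 or 2. Of 14 other structured RNA genes, 42.9% (Jurkat) to 64.3% (MCF7) had peaks without crosslinking. Spliceosomal snRNA genes had peaks in 10.9% (HEK293) to 34.8% (A549) of 46 genes without crosslinking, and in 65.2% in both UV lists. Over all 154 snRNA genes, leaving out peaks of p above 0.05 left differences with UV of 6.49 percentage points (-1.09 to 14.1) in HepG2 and 4.55 points (-3.28 to 12.4) in K562, in place of 13.6 in both, and both intervals include 0. The UV lists alone hold peaks above that value, so the filter could only lower these differences. SCARNA2, a guide RNA of Cajal bodies, carried 2 to 4 peaks in each list.

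The third comparison set the UV and non-crosslinked lists of HepG2 and K562 side by side. The UV lists also carried another score scale and other p-values, so the treatment could not be separated from the way the lists were made. The same line gave overlapping but not identical sites: 25.6% of genic HepG2 peaks without crosslinking overlapped a HepG2 UV peak, 2.48 on the log2 scale above shuffled peaks, and 45.2% of K562 peaks overlapped a K562 UV peak, 2.52 on the log2 scale above shuffled peaks (permutation p = 0.00995 in both, the smallest possible). The 2 percentages come from UV lists of different size, and with all lists thinned to the smallest they were 16.4% and 18.0%. Which UV list lay nearer could not be settled. Thinning lowers an overlap about in proportion to the share of the other list that is kept. It therefore lowers overlaps with the larger K562 UV list most, and the thinned order is not free of list size. K562 peaks without crosslinking lay 5.74-fold above shuffled peaks with K562 UV and 5.24-fold with HepG2 UV, but overlapped 18.0% and 21.3% in the thinned lists. HepG2 peaks without crosslinking lay at 5.57-fold with HepG2 UV and 5.97-fold with K562 UV, but overlapped 16.4% and 12% in the thinned lists.

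Ribosomal protein, chaperone and mitochondrial transcripts were denser in the HepG2 UV list than in the HepG2 list without crosslinking, which stood apart from the other lines by its low shares of ribosomal protein, chaperone and snoRNA genes. Ribosomal protein genes lay at a ratio of UV to non-crosslinked peaks per 10000 of 4.93 (exact conditional interval 3.60–6.89), heat shock and chaperone genes at 2.17 (1.47–3.28), snoRNAs and scaRNAs at 1.88 (1.56–2.28), glycolysis at 1.48 (1.06–2.09), translation factors at 1.46 (1.20–1.78) and liver markers at 1.35 (1.01–1.81). Mitochondrially encoded genes, with 94 peaks against 0 (63 without peaks of p above 0.05), were at least 25-fold higher, taking 3 counts for 0. The neuron list was lower, at 0.352 (0.178–0.664). Without peaks of p above 0.05 the interval for glycolysis included 1 (1.30, 0.921–1.85), as it did with peaks named X alone (1.29, 0.877–1.92). The same filter on p gave an interval that included 1 for spliceosomal snRNAs (1.51, 0.739–3.23), which lay at 2.03 with all peaks. In both lines this filter removes peaks from the UV list alone. A lower UV count after it, here and below, was the only change possible. In K562 the UV list was far larger, with 60096 peaks against 24115, and a ratio below 1 there is a lower share of the list. The snoRNAs and scaRNAs had 335 UV peaks against 306 and peaks in 302 genes against 276, mitochondrially encoded genes 75 peaks against 57, glycolysis 107 against 75 and proteasome subunits 155 against 86. As shares, the snoRNAs and scaRNAs lay at 0.439 (0.375–0.515), replication-dependent histones at 0.440 (0.339–0.572), mitochondrially encoded genes at 0.528 (0.369–0.759), glycolysis at 0.572 (0.422–0.780) and hnRNP genes at 0.635 (0.519–0.778). Without peaks of p above 0.05, mitochondrially encoded genes had 41 UV peaks against 57 (0.297, 0.194–0.451) and histones 94 against 114 (0.340, 0.256–0.451). Chaperones (0.669, 0.498–0.903), the nuclear-encoded respiratory chain (0.705, 0.558–0.894), abundant lncRNAs (0.721, 0.581–0.898) and proteasome subunits (0.723, 0.552–0.953) held lower shares too, and olfactory receptors a higher share at 1.98 (1.13–3.71), through OR51B5 with 55 UV peaks. With peaks named X alone, the intervals for the respiratory chain (0.634–1.12), proteasome subunits (0.591–1.17) and olfactory receptors (0.641–3.05) included 1. K562 ribosomal protein genes showed no detectable change (1.09, 0.896–1.32), nor did K562 erythroid markers (0.952, 0.765–1.19), SR factors in either line (0.949, 0.741–1.22 in HepG2 and 0.814, 0.639–1.04 in K562) or cell cycle genes (1.07, 0.851–1.36 and 0.880, 0.709–1.10). Translation factors lay at 0.851 (0.717–1.01) in K562, and at 0.831 (0.699–0.991), below 1, without peaks of p above 0.05.

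Single genes differed in both directions. Among HepG2 genes with 10 or more peaks over both lists, 193 of 1269 were at least 2-fold denser with UV and 260 at least 2-fold sparser. The genes named here have the most extreme ratios of many, so chance pushes their ratios away from 1. Highest with UV were CALR, a chaperone of the endoplasmic reticulum (16 UV peaks against 1, ratio 12.8, 1.98–536), the chaperonin gene CCT4 (13 against 1, 10.4, 1.56–441), PTMA and HNRNPA1 (12 against 1 each, 9.58, 1.42–410) and the mitochondrial chaperonin gene HSPD1 (11 against 1, 8.78, 1.28–378). PEG3, an imprinted zinc finger gene, and PLCB1 had 11 against 1, and NCAPD2, a condensin gene, 10 against 1. Sparser with UV were the carboxypeptidase gene CPD (1 against 15, 0.0532, 0.00126–0.346), LNPEP and SESN3 (1 against 12 each), KLF9 (1 against 11), and SLC25A36, SSR3, TMED7 and HECA (1 against 10 each). Of the 1269 genes, 12 had 0 UV peaks and 19 had 0 peaks without crosslinking. Taking 0 as 3 kept them out of the genes named. Among the 12 were PRPF8 (0 against 18) and PRRC2A (0 against 11). Without genes in the stretches lacking UV peaks described below, 2 genes with 0 UV peaks were left.

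In K562, 298 of 2081 genes were at least 2-fold denser with UV and 198 at least 2-fold sparser. With the lists thinned to the same size, 107 were denser and 113 sparser, so no balance between the directions can be read from these counts. Of the 2081 genes, 32 had 0 peaks without crosslinking, and taking 0 as 3 kept them out of the 8 highest ratios. Long non-coding RNA genes had 4 of the 8 highest ratios: LINC01344 (48 UV peaks against 1, ratio 19.3, 3.30–776), CCDC26, a lncRNA gene at 8q24 (39 against 1, 15.6, 2.65–634), LINC02476 (27 against 1, 10.8, 1.79–444) and MGC4859 (34 against 2, 6.82, 1.75–58.6). MKI67, the proliferation marker gene, had 25 UV peaks against 1 (10.0, 1.64–412), and SAMD5, FNDC3B and ARHGAP35 had 21, 19 and 18 UV peaks against 1 each. Genes sparser with UV included PRPF8 (0 against 21 peaks, ratio 0.0573 with 3 counts for 0, upper limit 0.0771) and PRRC2A (0 against 20, 0.0602, upper limit 0.0813). Others were the tumour antigen gene PRAME (0 against 16), the tRNA synthetase gene VARS1 (0 against 14), HYOU1 (0 against 12), HNRNPH1 (0 against 11) and the lactate transporter gene SLC16A1 (0 against 10). SLC12A7, a potassium-chloride cotransporter gene, had 2 against 8 peaks (0.100, 0.0104–0.503). PRPF8, PRRC2A, PRAME, VARS1, HYOU1 and SLC16A1 lay in stretches of the genome with no UV peak in either line.

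The longest of these stretches lay in the major histocompatibility complex on chromosome 6. From HLA-F to HLA-DPB1 (29723434–33089696, GRCh38), HepG2 held 179 peaks without and 2 with UV, a ratio of 0.00892 (0.00107–0.0327), and K562 held 184 peaks without and 0 with UV (upper limit 0.00813). The other 4 non-crosslinked lists held 212 (A549), 501 (HEK293), 497 (Jurkat) and 488 (MCF7) peaks there. Over the whole genome, 33 stretches held at least 20 HepG2 and K562 non-crosslinked peaks with no UV peak between them, over 23.6 Mb. Those outside chromosome 6 took in CANX and SQSTM1 on chromosome 5, CPSF1 and BOP1 on chromosome 8, and KANSL1 and MAPT on chromosome 17. The non-crosslinked lists placed 2.40% to 3.24% of their peaks in them, and the UV lists 5 (HepG2) and 2 (K562) peaks, at their edges. With other lines thinned to the number of UV peaks in place of the UV lists, 6 (A549 and HEK293) and 8 (Jurkat and MCF7) runs of 20 or more were left. The longest held 38 peaks. Stretches of up to 38 peaks, that of KANSL1 and MAPT (22) among them, could therefore come from list size.

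**Figure D4:**
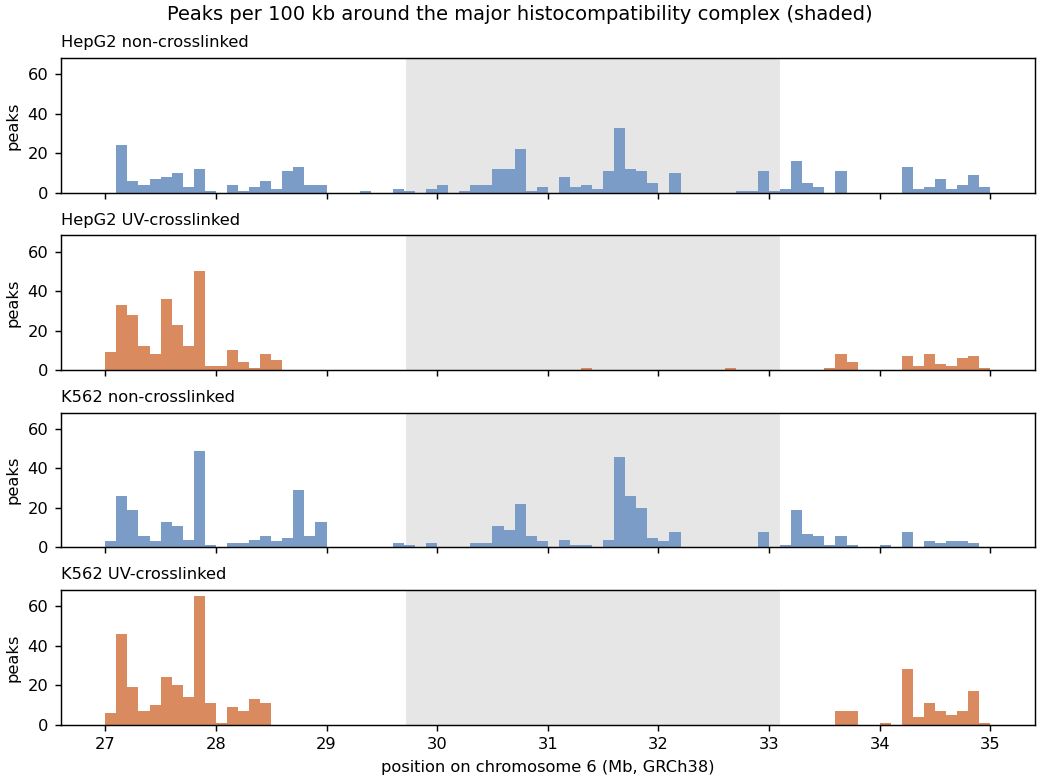
Number of peaks per 100 kb (vertical axes) along chromosome 6 (horizontal axis, Mb, GRCh38) in the HepG2 and K562 lists, blue without crosslinking and orange with UV, with the major histocompatibility complex shaded. The UV lists hold 2 and 0 peaks in the shaded region, against 179 and 184 without crosslinking.

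Transfer RNA genes carried peaks far more often in the UV lists. Peaks were present in 61.0% (56.4–65.4) of 451 tRNA genes in HepG2 UV and 55.7% (51.0–60.2) in K562 UV, against 19.1% in both lines without crosslinking and 14.6% to 20.8% in the other 4 lines. In HepG2 without crosslinking the p column was not read as a p-value, so a filter on p could not act on that list. The UV lists alone held peaks with a deposited value above 0.05 in this column, 923 in HepG2 and 1629 in K562. Leaving these out brought the shares to 26.2% (22.3–30.4) and 19.5% (16.1–23.4), and the difference from the non-crosslinked list was 7.10 percentage points (1.63–12.5) in place of 41.9 in HepG2, and 0.443 points in place of 36.6 in K562, with an interval that includes 0. With top scores alone the HepG2 difference was 2.44 points (-1.63 to 6.52), which includes 0 as well.

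**Figure D5:**
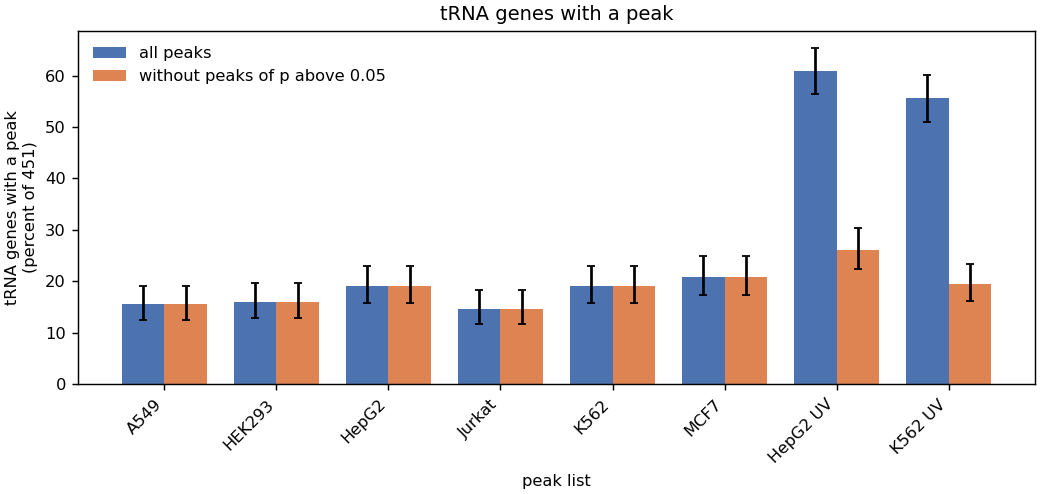
Percent of 451 tRNA genes with a peak (vertical axis) in each of the 8 lists, for all peaks (blue) and without peaks of p above 0.05 (orange), with 95% Wilson intervals. The UV lists hold 61.0% and 26.2% (HepG2) and 55.7% and 19.5% (K562). The other 6 lists hold no value above 0.05, but in HepG2 without crosslinking the column was not read as a p-value.

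The share of the list in small and structured RNAs differed with UV in opposite directions in the 2 lines, with 1497 peaks against 968 in HepG2 and 1324 against 1059 in K562. Without peaks of p above 0.05, a filter that removes UV peaks alone, these were 1222 against 968 and 1064 against 1059. The share of peaks in small and structured RNAs was 0.759 percentage points (Newcombe interval 0.476–1.04) higher with UV in HepG2, where it was 3.24% without. It was -2.19 points (-2.48 to -1.91) in K562, 2.20% against 4.39%. With that filter, the HepG2 difference was 0.108 points (-0.166–0.379) and no longer detectable.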

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

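Except for the tests of UV treatment gene by gene and of the processing of the UV lists, the tests in this part were chosen after the result was seen. Over the 6 non-crosslinked lists, 28 measures were tested for a list far from the others; chance gives about 1 in 20, and 7 measures had such a list.

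Ribosomal protein genes had peaks in 25% of genes in the HepG2 non-crosslinked list, far below the other 5 lists. A small list is not the reason, since the smaller K562 list had peaks in 78.6% (68.7–86.0) of them. Other protein-coding genes with 10 or more pseudogenes, counted by name, lay at 0.876 (0.747–1.02) of their density in the other lists, and genes without pseudogenes at 0.878. As a set, those 60 genes thus showed no such loss. They were not matched to the ribosomal protein genes in length, expression or likeness to their pseudogenes. Reads shared with pseudogenes therefore stay open for the ribosomal protein genes. A processing step of that list alone may account for the loss, because 99.2% of its p column lies below 0 and 0 other lists share this, but with a single such list it cannot be told apart from the library. The HepG2 UV list had peaks in 86.9% of these genes, and no biological explanation was tested. By density these genes were low in MCF7 too, at a ratio to the other lists of 0.495 (0.433–0.565), against 0.286 (0.209–0.383) in HepG2. A step of the HepG2 list alone would not cover MCF7.

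Genes with 5 or more HEK293 peaks and none in A549, Jurkat, K562 or MCF7 without crosslinking appeared in both HepG2 lists: of 35 such genes, 77.1% had a peak in HepG2 without crosslinking and 94.3% (81.4–98.4) with UV. Reads crossing between libraries of a flow cell are argued against, since HEK293 was on the other flow cell and the genes specific to A549, Jurkat and MCF7, on that same other flow cell, reached at most 15.4% in HepG2 UV; of 12 genes specific to K562, on HepG2's own flow cell, 7 had a peak in HepG2 without and 9 with UV (46.8–91.1%). HEK293 RNA in both HepG2 libraries could give this pattern, with the 35 genes at 0.675 of their HEK293 density with UV and 0.573 without. Of the 35 genes, 9 without UV and 7 with UV lay at or above their HEK293 density. These counts cannot decide on a single common fraction, because most of the genes hold few peaks. In BMP2 and RGMA, 2 peaks in HepG2 against 5 in HEK293 already count as above. NEFM had 7, 8 and 3 peaks and IRS4 54, 8 and 29 in HEK293, HepG2 and HepG2 UV, both picked from the 35. Expression by HepG2 itself was not tested and stays open.

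Long stretches of the genome, most of the major histocompatibility complex among them, held no UV peak away from their edges. Fewer peaks in the UV lists are argued against for the longest stretches. Other lines thinned to the number of UV peaks left a longest run of 38 peaks, against 231. They also left 6 and 8 runs of 20 or more, so list size stays open for stretches of up to 38 peaks. For UV acting gene by gene, 24 neighbouring pairs of K562 genes lost all UV peaks together, and the highest of 200 shuffles gave 8. Stretches that span many genes already imply such neighbours. The count restates the pattern and cannot decide on this cause. The processing of the UV lists may be the source but stays open: stretches found from K562 alone lay at a ratio of 0.0269 (0.0161–0.0424) in HepG2, but 540 of their 564 HepG2 peaks lay in the stretches already known to be empty, and the rest gave 0.599 (0.306–1.15). Neither an effect of UV on the same regions in both lines nor an alignment of the UV reads to other reference sequences, such as alternate copies of these regions, was tested.

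Of the hnRNP genes, 76.7% had a peak in HepG2 without crosslinking, the list farthest from the others. SR and SR-like factor genes were lowest in K562, at 88.2%, a difference of 1 gene from the other 5 lists. Heat shock and chaperone genes were lowest in HepG2, at 73.3%. The snoRNA and scaRNA genes were lowest in HepG2, at 25.9%. Abundant lncRNAs were lowest in HepG2, at 36.4%. Olfactory receptor genes were lowest in A549, at 0.513%, 2 genes against 4 or 5 in the other lists.

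Several measures differed with UV in opposite directions in HepG2 and K562, and the difference between the lines was not tested. These are shares of lists of different size, and peaks in snoRNAs and scaRNAs (158 to 373, 306 to 335) and glycolysis genes (56 to 104, 75 to 107) were more numerous with UV in both lines. The protein-coding share differed by -2.02 points in HepG2 and 1.96 points in K562. The small and structured RNA share differed by 0.759 and -2.19 points, and by 0.108 points (-0.166–0.379) in HepG2 without peaks of p above 0.05. The share outside gene spans differed by 0.826 and -0.537 points. In HepG2 it differed by 0.575 points (-0.0856–1.23) with peaks named X, which includes 0, and by 3.43 points counted by bases. UV ratios were 1.48 and 0.572 for glycolysis genes, and the HepG2 interval included 1 with peaks named X (0.877–1.92) and without peaks of p above 0.05 (0.921–1.85). They were 2.17 and 0.669 for heat shock and chaperone genes. For snoRNAs and scaRNAs they were 1.88 and 0.439.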

How the results depend on the processing

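The alternatives that leave out peaks named other than X, peaks of p above 0.05, stretches without UV peaks or scores below the top, and the shifts, were chosen after seeing the data. The filter on p removes peaks from the UV lists alone. All 15 pairs of lines stayed above shuffled peaks with 50% overlap, strand ignored, peaks named X and shifted peaks, and the HepG2 and K562 UV overlaps did so in all settings run. Marker lists stayed highest in their own line in 6 of 6 with thinned lists and with peaks named X, the alternatives run for them. Merging overlapping peaks changed no list size by as much as 1.5 times, and all peaks lay on the main chromosomes. Gene lists above the random range numbered 94 both thinned and with peaks named X, and those below 41 and 40.

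Counted by bases, the protein-coding share was 84.9% in A549, 85.7% in HEK293, 85.3% in HepG2, 87.3% in Jurkat, 78.9% in K562, 89.3% in MCF7, 78.7% in HepG2 UV and 80.7% in K562 UV. Sites in all 6 lines numbered 1093 with peaks named X, 21 with thinned lists, 975 with 50% overlap and 3158 without HepG2; thinning leaves fewer peaks to meet, and leaving a line out asks for fewer lines. The small RNA difference with UV was 2.42 points (peaks named X), 0.108 (without p above 0.05) and 2.09 (bases) in HepG2, and -3.27 and -2.57 points (peaks named X, without p above 0.05) in K562; the cause was not tested. The tRNA difference was 7.10 points in HepG2 and 0.443 in K562 without p above 0.05, and 2.44 (-1.63–6.52) and -3.77 points (-7.64–0.0612) with top scores alone, which ends the call in HepG2 and reverses K562 within counting error; such peaks hold most tRNA peaks of the UV lists. Genes at least 2-fold denser with UV numbered 96 (HepG2) and 107 (K562) with thinned lists and 56 and 125 with peaks named X, and sparser genes 148 and 113, then 77 and 83; fewer genes reach 10 peaks, and the turned balance in K562 thinned was not explained. Of 62 named gene ratios under 2 filters 48 stayed within their interval, and of 95 gene list ratios 93.

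No paired analysis was possible because each group has a single peak list and no value per replicate, and leaving out replicates and count tests were not run for the same reason. The better part of each list by p or score was not run, since over 96% of scores tie in all lists and of p-values in 7, and the eighth holds values below 0. Exon-based alternatives, motifs and shuffles within exons or introns were not run without exon positions.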

Other observations

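The genes and windows in this part were chosen after their values were seen. Windows of 2 Mb on the autosomes with 30 or more peaks were ranked per line by their density over the median of the other 5 lines. A median below the density of 3 peaks in the largest of those lists was raised to it, which lowers the fold. The genes below come from the top 5 windows per line, with peaks counted over the whole gene. Only protein-coding and lncRNA genes with names not starting with LOC were looked at. Ribosomal and other small RNA genes and pseudogenes were left out. The highest fold of all was in MCF7 on chromosome 21 from 10000001 to 12000000 (231 peaks, 74.3-fold), where TPTE, the only gene of these kinds with a peak, held 5. In A549 the highest fold was on chromosome 21 from 8000001 to 10000000 (63 peaks, 32.6-fold), a window that stood out in HEK293 too (31 peaks, 10.6-fold). No protein-coding or lncRNA gene looked at had a peak there, and what its peaks lie in was not analysed. The next windows in A549 pointed to CYP24A1 (82 peaks, window 28.2-fold) and the focal adhesion gene TNS3 (147 peaks, window 23.7-fold). In HEK293 the axon guidance gene SLIT2 had 124 peaks (window 14.2-fold). In Jurkat they held IKZF2, a lymphoid transcription factor gene, with 75 peaks (15.2-fold), the microRNA host gene MIR181A1HG with 55 beside PTPRC with 39 (14.6-fold), and RUNX1 with 119 (4.60-fold). In MCF7 they held TRPS1, a luminal transcription factor gene, with 90 peaks (31.2-fold over the raised median), GATA3 with 55 (16.1-fold) and the semaphorin gene SEMA3C with 195 (15.1-fold). Between TRPS1 and GATA3 ranked chromosome 1 from 106000001 to 108000000 (192 peaks, 27.5-fold), with 20 each in PRMT6 and VAV3. That window was in Jurkat's top 5 too (54 peaks, 7.77-fold), with 46 in VAV3. In HepG2 the first 4 windows were led by DSG2 (17 peaks, 3.54-fold), AKT3 (17 peaks, 3.46-fold), HECA (10 peaks, 3.12-fold) and APOB (27 peaks, 2.86-fold). In K562 the densest was chromosome 22 from 20000001 to 22000000, with 209 peaks (4.18-fold) spread over 28 genes, CRKL with 17 and MED15 and MAPK1 with 15 each; the adjoining windows lay at 3.91-fold and 2.95-fold, the latter with BCR (16 peaks).

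MicroRNA genes had peaks in every list, from 442 of 1913 genes in K562 (23.1%) to 592 in A549 (30.9%) without crosslinking. Of the 1913 genes, 166 had a peak in all 6 non-crosslinked lines and 138 in all 8 lists. MIR142, a microRNA of blood cells, and MIR200C, an epithelial microRNA, each had a peak in all 8 lists.

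Ribosomal protein genes with a snoRNA inside them lay at 0.194 (0.106–0.327) of their density in the other lists in HepG2 without crosslinking, and those without at 0.361 (0.246–0.512). lncRNA genes that hold a snoRNA lay at 0.199 (0.0854–0.394) there, and at 1.06 (0.781–1.40) in HepG2 UV.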
